A study of Homo sapiens with 6 samples.

How the data were processed

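Single cells of the human induced pluripotent stem cell line KOLF2.C1 were profiled by droplet RNA sequencing in 6 libraries, titled BS16001, BS16007, BS16012, BS16017, PR17028 and PR19058. Per the labels' protocols, the cells were passaged as single cells, treated with the growth factor BMP4 and with SU5402, an inhibitor of FGF receptors, and harvested at several times. No label gives the treatment or time of a library, so the libraries could not be grouped. Whether any are replicates of each other is not known, and no test between them was possible. The library titles are used as names only. Per the labels' protocols the Chromium v2 chemistry was changed to make a hashtag library as well. Hashtag counts were not used here, so each library may mix several conditions, and no cell could be assigned to one.

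The deposited values are counts: whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization. Per the submitters' processing notes, reads were handled with bcl2fastq 2.16.0.10 and Cell Ranger on genome build GRCh38, and per the file headers the software version was 3.1.0. The barcodes in the files had already been called as cells. The gene annotation the authors counted against is not stated. The files list 33538 genes, of which 33456 identifiers were found in GENCODE release 29, the source of the GRCh38 coordinates given. Of all listed genes, 24 share a symbol with another, and 2 symbols of the gene lists, H19 and ALPPL2, are not in the files.

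Barcodes were kept with at least 500 genes detected and at most 20% mitochondrial UMIs. Of 25962 deposited barcodes, 2202 had fewer genes and 1061 more mitochondrial UMIs, and 22699 passed. Scrublet, as in scanpy, was run on each library and called 43 of these as doublets. A caller that marks so few of so many cells has not worked, so the kept cells are to be read as cells with doublets. The 22656 kept cells hold 651310804 UMIs. Counts were summed over the kept cells of a library, or of a cluster within a library, and given as CPM, the usual depth-scaled unit, over all UMIs of those cells, with exact 95% Poisson intervals. Shares of cells carry exact 95% Clopper-Pearson intervals. Both cover counting error only. A count of 0 was read as allowing up to 3 counts, which is 0.0180 CPM in PR19058, the deepest library, and 0.0848 CPM in PR17028, the shallowest.

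All kept cells were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 highly variable genes were chosen, and 30 principal components, 15 neighbours and Leiden resolution 1 were used. The genes of the description lists, mitochondrial, ribosomal-protein and sex-chromosome marker genes were kept out of the highly variable genes. Clusters were named from 15 marker lists of 12 genes each: pluripotent, primitive streak, emergent mesoderm, extra-embryonic mesenchyme, amnion, trophoblast, definitive endoderm, hypoblast or yolk sac endoderm, endothelium, blood, primordial germ cell, neural, surface ectoderm, cardiac and smooth muscle. A marker counted as raised at 20 CPM or more and at least 2-fold over all other kept cells, with 10 CPM added to both sides. A cluster took the name of the list with most raised markers if there were at least 3, without a tie, and if no other list had more markers among its top 10 genes by fold. A cluster with a median UMI number below 1/3 of its own library's also needed a marker of that list among those 10 genes. This naming rule was set after the clusters were seen. The marker lists were not changed.

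The 23 description lists hold 304 genes. They cover BMP response, BMP ligands and receptors, FGF-ERK response, FGF ligands and receptors, WNT response, WNT ligands and antagonists, and NODAL response. Others cover epithelial genes, mesenchymal transition, collagen and matrix, basement membrane, mesoderm transcription factors, anterior HOX and posterior HOX genes. The rest cover syncytiotrophoblast, imprinted genes, naive pluripotency, S phase, G2/M phase, p53 targets, immediate early and heat shock, hypoxia and glycolysis, and cholesterol synthesis. Between cell sets of 1 library, each gene with at least 10 UMIs in both sets together was given a log2 ratio of CPM with 0.5 counts added. A list was summarised by its median, the interval of that median under redrawn Poisson counts, and its percentile among 10000 random lists of the same size matched on mean expression. The percentile describes these libraries and is no test. Where a gene had 0 UMIs in a set, the list median was also computed with that gene at its 3-count bound. Named classes needed 50 cells or more in a library.

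For pairs of markers in 1 cell, each cell was thinned to 2000 UMIs at random. That leaves out 205 shallower cells of BS16001, 95 of BS16007, 387 of BS16012, 939 of BS16017, 618 of PR17028 and 20 of PR19058. The number of cells with both genes was divided by the number expected from both shares. The ratio is given where at least 10 cells were expected.

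Genes were named by a fixed rule: up to 4 per list with the highest CPM in any library, the genes TBXT, MIXL1, EOMES, POU5F1, SOX2, NANOG, ISL1, GABRP, HAND1, GATA3, CDX2, FOXF1, BST2, CGA, SOX17, FGFR1, DUSP6 and ID1, and 10 genes each with the largest and smallest ratio between libraries among genes outside the lists at 100 CPM or more. For a pair of cell sets, the rule takes up to 4 genes per description list with the largest log2 ratio in either direction. The lists, the naming of genes, the cell filters, the thinning depth and the alternative settings listed next, apart from the last pair, were chosen before the data were examined.

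The alternative settings were all deposited barcodes, a stricter filter of at least 1500 genes and at most 10% mitochondrial UMIs, doublet calls kept, Leiden resolutions 0.5 and 2, highly variable genes with the description lists, and each library clustered on its own. Scaling was also done without mitochondrial and ribosomal-protein genes, with edgeR's TMM factors, with DESeq2's size factors, and as the mean over cells of each cell's CPM. List medians were also taken over members with at least 50 UMIs and with every cell thinned to 2000 UMIs, and co-detection with 4000 UMIs and without thinning. Removing the highest Scrublet scores at 0.8% per 1000 cells, and comparing pairs of clusters by number, were added after seeing the data.

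The steps were tested on simulated data drawn from the real means and depths. In 2000 simulated cells of 2 populations at the depth of BS16012, 91.6% lay in a cluster led by their own population, and 97.7% of the 1726 cells with at least 4000 UMIs did. A mixed cluster of 351 cells had a median of 1813 UMIs, so clusters of such shallow cells can join populations. Of the population with raised markers 83.2% was named for them, and 0.1% of the other. Every marker of the amnion list was raised there, an easier case than the real cluster 5, which was named on 3. Intervals of list medians held the true value for 99.5% of 200 lists. Apart from depth, simulated cells of a population varied by counting error only, which is the error these intervals redraw. This coverage thus followed largely from the construction, and coverage for real clusters was not tested. Of the same lists, 2.5% fell outside the random range. These lists could hold changed genes, so this share is no rate of false calls. For 20 independent gene pairs the co-detection ratio had a median of 0.988 with thinning and 1.10 without.

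The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. The random seed was 0.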

Results

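The 6 libraries hold cells of KOLF2.C1, a human induced pluripotent stem cell line, from a study that treated such cells with BMP4 and an inhibitor of FGF receptors. The question, from the study's title, is where extra-embryonic mesenchyme, the connective tissue outside the embryo proper, comes from. The genes of pluripotent cells, primitive streak, mesoderm, mesenchyme, amnion and trophoblast were therefore measured in each library. No label assigns a time or treatment to a library, and it is not known whether each library was treated. Each value therefore describes 1 library, and no replicates are known.

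Kept cells numbered 3129 in BS16001, 4725 in BS16007, 3920 in BS16012, 5819 in BS16017, 2055 in PR17028 and 3008 in PR19058. They held 107133665, 134328564, 118491864, 88884576, 35383048 and 167089087 UMIs in that order. The median UMIs per cell were 31412, 25843, 27386, 12883, 11912 and 49582. That of PR17028 depended on the filter, with 2099.5 over all deposited barcodes and 24692 under the stricter filter. Median genes detected per cell ran from 2581 in PR17028 to 6519.5 in PR19058. PR19058 shared only 1 barcode in its 5 pairs with other libraries, against 283 in the other 10 pairs. Its chemistry may differ from theirs, so its depth and levels may not compare with theirs. In PR17028, 947 of 3354 deposited barcodes had too few genes and 352 too many mitochondrial UMIs. Ribosomal-protein genes took a median of 20.5% of a cell's UMIs in PR19058 and 35.2% in BS16007. Gene levels are depth-scaled UMI counts (CPM), and intervals cover counting error only.

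Pluripotency genes were high in BS16001 and BS16007, and trophoblast hormone genes in BS16017 and PR17028. Primitive streak genes were almost absent from every library, while HAND1, LUM, IGFBP3 and GABRP, from the mesenchyme and amnion lists, were abundant in BS16012, BS16017 and PR19058. POU5F1 (ENSG00000204531, GRCh38 chromosome 6, 31164337 to 31180731, minus strand) stood at 1630.5 CPM in BS16001, with an interval of 1623 to 1638, and at 1352 in BS16007. It stood at 140.5 CPM in BS16012, 191 in PR19058, 12.7 in PR17028 and 5.02 in BS16017. SOX2 had 246 CPM in BS16001, 114 in BS16007 and at most 1.32 in the others, with 0 UMIs in PR17028, which allows up to 0.0848 CPM. NANOG was lower, at 13.4 CPM in BS16001 and 4.0 in BS16007. L1TD1 went another way than SOX2, with 118 CPM in BS16001 and 452 in PR19058. TERF1 ran from 24.5 CPM in PR17028 to 432 in BS16001.

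TBXT, the classical gene of the primitive streak (ENSG00000164458, chromosome 6, 166157656 to 166168700), had 0 UMIs in BS16012, BS16017 and PR17028. This allows up to 0.0253, 0.0338 and 0.0848 CPM. Its highest level was 0.0373 CPM, in BS16001. EOMES reached 0.159 CPM and MIXL1 1.72 CPM at most. Of the 12 primitive streak genes, 11 stayed under 5 CPM in every library, and the other, CDX1, reached 38.6 CPM in BS16012. Of the 12 emergent mesoderm genes, 7 stayed under 5 CPM in every library, and TBX3 was highest, at 289 CPM in BS16017. A transient stage between the sampled times would leave no trace in these libraries.

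Mesenchyme genes did not move as a set. HAND1 (ENSG00000113196, chromosome 5, 154474972 to 154478264) reached 1213 CPM in PR19058 and 822 in BS16017, against 21.4 in BS16001. LUM (ENSG00000139329, chromosome 12, 91102629 to 91111831), which encodes the matrix protein lumican, had 1614 CPM in BS16017 and 177 in BS16012. COL3A1 reached 51.5 CPM in BS16017. FOXF1, a mesenchymal transcription factor, stayed at or below 0.112 CPM, with 0 UMIs in BS16012, BS16017, PR17028 and PR19058, which allows up to 0.0848 CPM in the shallowest of these. BST2 went the other way from LUM, with 75.4 CPM in BS16007 and 0.425 in PR19058. Of the 12 extra-embryonic mesenchyme genes, 3 stayed under 5 CPM in every library.

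The amnion genes IGFBP3 and GABRP were abundant in BS16012 and BS16017, where LUM was too. The amnion list as a whole also summed to 1046 CPM in PR17028, with 5 genes at 20 CPM or more, where the mesenchyme list summed to 91.2. In BS16007, 4 amnion genes reached 20 CPM. IGFBP3 (ENSG00000146674, chromosome 7, 45912245 to 45921874) had 2176 CPM in BS16017, 1472 in PR19058 and 1264 in BS16012. GABRP had 409 CPM in BS16012 and 381 in BS16017, against 0.971 in BS16001. ISL1, a gene of both amnion and cardiac progenitors, ran from 0.848 CPM in PR17028 to 56.8 in BS16017. CGA, the alpha chain of glycoprotein hormones (ENSG00000135346, chromosome 6, 87085498 to 87095406), had 23260 CPM in PR17028 and 16821 in BS16017, against 0.0747 in BS16001. ERVW-1, the syncytin gene, had 1052 CPM in PR17028. GATA3 lay between 58.7 CPM in BS16001 and 989 in PR17028, and KRT7 between 23.4 and 1560.4. As a mean over cells of each cell's CPM, 25 of 765 gene levels of at least 5 CPM moved by more than 1.5-fold, those of CGA in BS16017 and of LUM in BS16012 among them. Without mitochondrial and ribosomal-protein genes, each CPM rose by 1 factor per library, from 1.33 to 1.64. Over the marker lists, 3 amnion and 1 trophoblast gene of 12 each stayed under 5 CPM in every library, and 1 of 12 pluripotency genes.

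**Figure D1:**
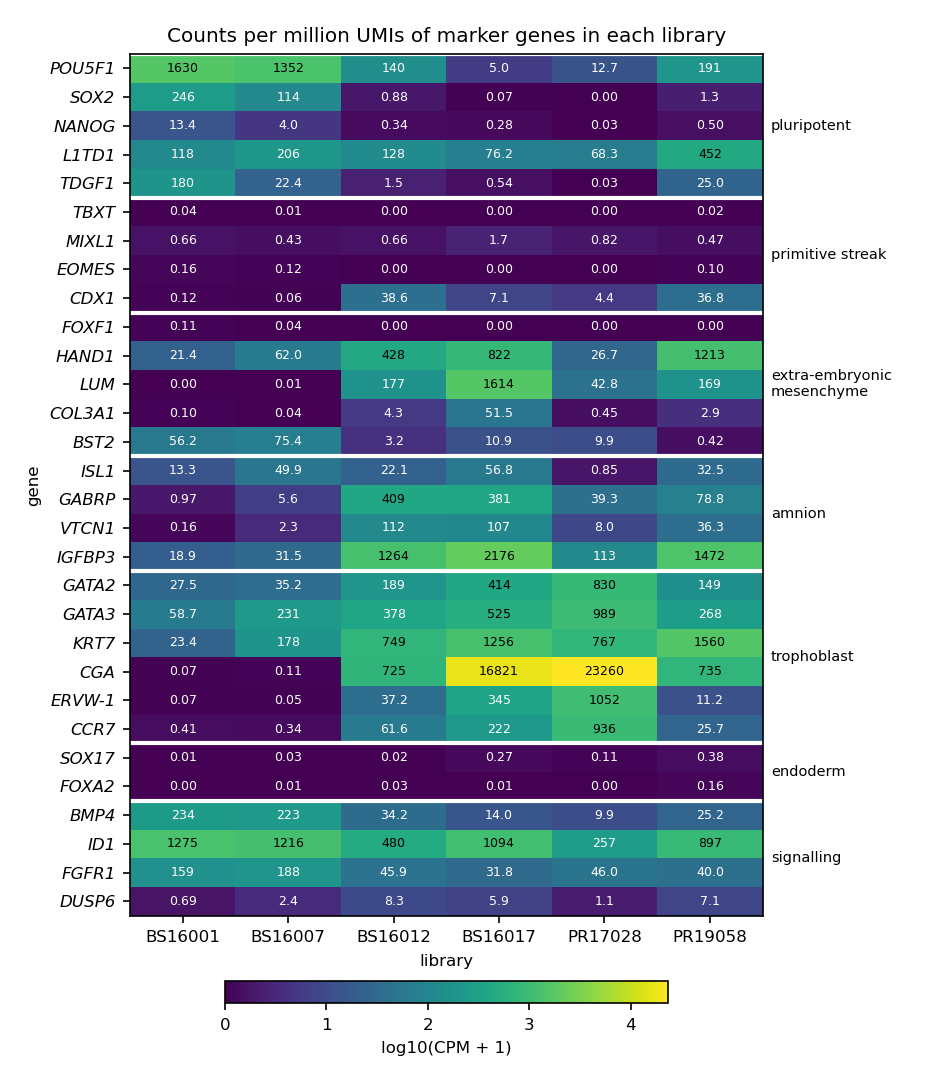
CPM of marker genes (y axis) in each of the 6 libraries (x axis), with the value in each cell and the colour on a log10 scale of CPM plus 1. POU5F1 is at 1630.5 CPM in BS16001, TBXT at or under 0.0373 everywhere, and CGA at 23260 in PR17028.

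Most genes of the endoderm, endothelium, blood and neural lists were low, while several smooth muscle genes were not. SOX17, the gene of endoderm and germ cells, stayed at or below 0.377 CPM. In the definitive endoderm list, 9 of 12 genes stayed under 5 CPM in every library and STC1 was highest, at 49.0 CPM. For hypoblast or yolk sac endoderm the numbers were 8 of 12 and APOA2 at 101 CPM, for endothelium 8 of 12 and EGFL7 at 109.6, and for blood 11 of 12 and RUNX1 at 24.5. Primordial germ cell genes gave 6 of 12 with KLF4 at 77.9 CPM, neural genes 10 of 12 with DLX2 at 30.1, and cardiac genes 6 of 12 with MYL7 at 70.6. Surface ectoderm genes gave 4 of 12 with PERP at 832 CPM, and smooth muscle genes 3 of 12 with CALD1 at 2282. In PR19058 the smooth muscle list summed to 5319 CPM, with 6 genes at 20 CPM or more, against 2953 for trophoblast and 1923 for amnion. The same list summed to 3143 CPM in BS16017, 2767 in BS16001, 2235 in BS16012, 684 in BS16007 and 641 in PR17028. It was thus also high in BS16001, where pluripotency genes were high, so its sum alone marks no cell type. PERP and CALD1 are active in many cell types.

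Targets of the BMP and FGF pathways were measured in each library. ID1, a direct target of BMP, ran from 257 CPM in PR17028 to 1275 in BS16001, and was the highest of the BMP response list, of which 1 of 12 members stayed under 5 CPM in every library. BMP4 itself had 234.5 CPM in BS16001 and 9.95 in PR17028. FGFR1, a receptor that SU5402 blocks, ran from 31.8 CPM in BS16017 to 188 in BS16007, while DUSP6, a target of the FGF-ERK pathway, stayed between 0.691 CPM in BS16001 and 8.28 in BS16012. CDX2 was highest in BS16007, at 16.1 CPM. No untreated library is labelled, so these levels have no baseline.

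The other description lists had their highest genes as follows. IER3 of the FGF-ERK list reached 218 CPM, AXIN2 of the WNT response 18.8, SFRP1 of the WNT ligands and antagonists 567 and SKIL of the NODAL response 148. KRT18 of the epithelial list reached 8671 CPM, VIM of mesenchymal transition 1265 in BS16001, FBLN1 of collagen and matrix 1143 and COL4A1 of basement membrane 192. The mesenchymal transition list as a whole was also highest in BS16001. It summed to 1892 CPM there, against 1091 in BS16017, 989 in PR19058 and 526 in BS16012. NR2F2 led the mesoderm transcription factors at 149 CPM, HOXB2 the anterior HOX genes at 27.5 and HOXB6 the posterior HOX genes at 8.98. ERVV-1 led the syncytiotrophoblast list at 497 CPM, PHLDA2 the imprinted genes at 1489, and ZFP42 the naive pluripotency genes at 123. For the cell state lists they were TYMS for S phase at 158 CPM, CCNB1 for G2/M phase at 318, GDF15 for p53 targets at 1124, HSPB1 for immediate early and heat shock at 5225, BNIP3 for hypoxia and glycolysis at 1221, and SC5D for cholesterol synthesis at 368. IGF2, PEG3, GDF1 and several HOXC genes had 0 UMIs in all libraries. Each of them overlaps another gene on the same strand, which Cell Ranger's counting may leave uncounted, so their absence cannot be read.

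Outside the lists, PRR9 and HOPX were among the genes with the widest range over the libraries, and NDUFB10 and SF3B5 among those with the narrowest. PRR9 ran from 0 UMIs in BS16001 and BS16007, at most 0.0280 and 0.0223 CPM, to 1417 CPM in PR17028, and HOPX from 0.121 CPM in BS16001 to 3141 in PR17028. KRT23, LGALS16, S100P, BCAR4, GAST, SLN and AC108752.1 were also among the 10 with the largest ratio. The long RNA AC106864.1 went the other way, with 863 CPM in BS16001 and 0 UMIs in PR17028. NDUFB10, a subunit of respiratory complex I, lay between 232 and 257 CPM, and SF3B5 between 139 and 162. MRPL14, NDUFB8, COX6B1, CUTA, NEDD8, NDUFS8, FAU and TRMT112 were the others with the smallest ratio.

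Clustering gave 16 clusters, of which 7 could be named: 2 pluripotent-like, 1 amnion-like and 4 trophoblast-like. No cluster was named for primitive streak, mesoderm or mesenchyme, and none for smooth muscle. At Leiden resolution 2, however, 9.07% of BS16017 was extra-embryonic mesenchyme-like, and at 0.5, 94.6% of PR19058 was smooth muscle-like. Cluster 0 was pluripotent-like and was led by APELA, VIM, TDGF1 and SOX2. Cluster 5 was amnion-like and was led by GABRP, with VTCN1 and IGFBP3 also raised. Cluster 8 was trophoblast-like and was led by HOPX, PRR9, KRT23, CCR7 and ERVW-1, and cluster 15 by PAGE4 and HLA-G. Clusters 2, 9 and 13 took a pluripotent-like or trophoblast-like name at medians of 1595, 2215 and 1825 UMIs. Nuclear NEAT1 was among the genes that lead cluster 13. The leading genes define the clusters and are no results about them.

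The 9 unnamed clusters held 61.4% of the kept cells. Cluster 11, with 2578 of its 2640 cells from BS16017, was led by TGFBI, LUM, CPE and MMP2. It had 6 raised genes each of the mesenchyme and amnion lists and stayed unnamed because of this tie. Cluster 7, mostly of PR19058, was led by NTS, NPPB and NNMT and had 4 raised smooth muscle genes, but only HAND1, of the mesenchyme list, stood among its top 10 genes. Clusters 6, 12, 1, 3 and 4 were led by ISG15 and CCKBR, by GJA5 and GSTM3, by UPK2 and PCAT14, by B3GNT7 and SOX11, and by CLDN10 and FEZ1. Clusters 10 and 14 had 10 and 6 raised trophoblast genes at medians of 1474 and 3698 UMIs. They stayed unnamed because no trophoblast marker was among their top 10 genes, which the rule asks of shallow clusters. A cluster with 95% or more of its cells from 1 library, as clusters 0, 1, 3, 5, 7, 11, 12, 14 and 15 have, may be that library and not a cell type.

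**Figure D2:**
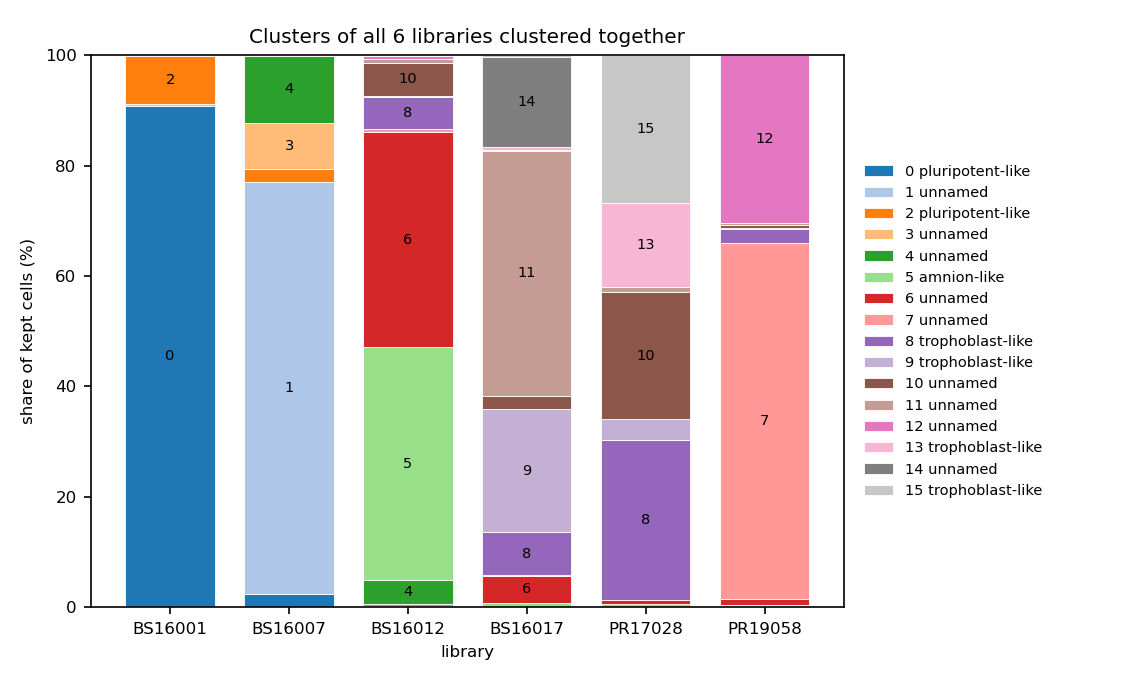
Share of kept cells in percent (y axis) in each of 16 clusters, stacked per library (x axis), with all 6 libraries clustered together. Cluster 0 holds 90.9% of BS16001, cluster 1 holds 74.6% of BS16007 and cluster 7 holds 64.4% of PR19058.

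Pluripotent-like cells filled BS16001, amnion-like cells took a large part of BS16012, and trophoblast-like cells the most of PR17028. In BS16001, 3114 of 3129 cells were pluripotent-like, 99.5% (99.2 to 99.7), and in BS16007 225 of 4725, 4.76% (4.17 to 5.41). Cluster 1, with 74.6% of BS16007, had 3 raised pluripotency genes, POU5F1, SOX2 and DPPA4, and POU5F1 in 91.8% of its thinned cells. It stayed unnamed because BST2, of another list, was among its top 10 genes and none of these was. Other cluster settings moved the named shares to between 51.4% and 98.1% and to between 0% and 3.87%. Amnion-like cells were 1654 of 3920 in BS16012, 42.2% (40.6 to 43.8), and between 19.1% and 66.1% under other settings. Trophoblast-like cells were 1534 of 2055 in PR17028, 74.6% (72.7 to 76.5), and 1803 of 5819 in BS16017, 31.0% (29.8 to 32.2). Of the latter 1291 lay in cluster 9, at a median of 2140 UMIs, where free RNA is not ruled out, which is 22.2% of the library against 7.84% in cluster 8. In PR17028, 312 lay in cluster 13, 15.2% of the library, where the nuclear RNAs MALAT1 and NEAT1 stood at 10.5 times their share in cluster 8. Another 474 cells of PR17028, 23.1%, lay in the unnamed cluster 10, which had 10 raised trophoblast genes, at a median of 1293 UMIs there. Trophoblast-like cells also made up 241 of 3920 in BS16012, 6.15% (5.42 to 6.95), and 82 of 3008 in PR19058, 2.73% (2.17 to 3.37). Other settings gave 91.3% to 98.3% in PR17028, 18.3% to 41.1% in BS16017, 4.34% to 29.1% in BS16012 and up to 15.6% in PR19058. None of the 3129 cells of BS16001 or the 4725 of BS16007 was trophoblast-like, which allows shares of up to 0.118% and 0.0780%. Unnamed cells made up 0.479%, 95.2%, 51.3%, 68.2%, 24.8% and 96.9% of the libraries, in the order given above. The rule that left them unnamed was set after the clusters were seen.

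BS16012 was the only library with 2 named classes of at least 50 cells, and its amnion-like cells were compared with its trophoblast-like cells. The amnion-like cells had far less RNA of syncytiotrophoblast genes, and more of dividing, mesenchymal and matrix genes. The compared genes had no part in the clustering, but the clusters come from the same cells, so the ratios describe these sets and were not tested. Marker genes could take part in the clustering, and the trophoblast-like name rests on CGA and ERVW-1 among others. ERVV-1, of the syncytiotrophoblast list, is itself among the top 10 genes of cluster 8. The direction of the syncytiotrophoblast list was thus partly set by how the classes were made and named. The trophoblast-like cells of cluster 8 had a median of 46543 UMIs and the amnion-like cells 27926.5, and doublets among the former were not removed. Median mitochondrial shares were 5.83% and 3.62%, and ribosomal-protein shares 25.6% and 33.75%, in that order. What these differences add to the ratios was not separated.

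The syncytiotrophoblast median was a log2 ratio of -5.36 (-5.64 to -4.94), with 7 of 8 genes at least 2-fold lower and none higher, at percentile 0 of the random lists, and it was -3.38 at Leiden resolution 0.5. ERVFRD-1 had 0.480 CPM in amnion-like and 102 in trophoblast-like cells, and ERVV-1 had 2.67 and 536. The G2/M phase median was 1.65 (1.47 to 1.76), with 11 of 13 genes at least 2-fold higher, but 0.64 at resolution 0.5. CENPF stood at 109 against 19.9 CPM. The S phase median was 0.77. The mesenchymal transition median was 1.47 (1.37 to 1.99) with 7 of 11 genes higher and 2 lower. VIM (ENSG00000026025, chromosome 10, 17228259 to 17237593) had 244 CPM against 6.98, while TWIST2 had 0.211 against 26.5. The collagen and matrix median was 1.19 (0.81 to 1.72), with TNC higher at 30.2 against 2.27 CPM and BGN lower at a log2 ratio of -5.49. Mesoderm transcription factors had a median of 2.62, or 0.93 with genes at 0 set to their bound, and MEIS1 stood at 22.4 against 1.36 CPM. Anterior HOX genes had 3.17, or 2.67 at the bound, with HOXB2 at 38.6 against 4.26 CPM.

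Imprinted, stress and signalling genes went both ways in this pair. CDKN1C, an inhibitor of the cell cycle, had 35.7 CPM in amnion-like and 1469 in trophoblast-like cells, and PHLDA2 had 14.5 and 1300, with a list median of -0.52. GDF15 fell by 6.27 on the log2 scale, with a p53 target median of -0.44. The BMP response median was -0.64 and its mean 0.26, since NOG and ID3 were higher, at 4.0 and 3.05, and MSX2 lower, at -3.03. This median turned to 0.47 at Leiden resolution 0.5. The FGF-ERK median of -0.83 turned to 0.07 at Leiden resolution 0.5 and to 0.24 with thinned cells. FGF18 had 0.154 against 62.1 CPM. Medians were 1.21 for BMP ligands and receptors, 0.57 for FGF ligands and receptors, 0.35 for WNT response, 1.26 for WNT ligands and antagonists and 0.82 for NODAL response. With thinned cells the FGF ligand median turned to -0.61. They were 0.08 for epithelial, 0.39 for basement membrane, 1.43 for naive pluripotency, -0.77 for immediate early and heat shock, -0.10 for hypoxia and glycolysis and 0.30 for cholesterol synthesis genes. The means of the lists of FGF ligands, WNT response, WNT ligands, epithelial, basement membrane and naive genes had the other sign, at -0.29, -0.53, -0.30, -0.03, -0.01 and -0.06. Over other settings the NODAL median ran from 0.46 to 1.61, the mesoderm factors from 1.63 to 2.78 and the anterior HOX genes from 2.54 to 3.29. The epithelial, basement membrane, naive and hypoxia medians also changed sign, to -0.07, -0.09, -0.12 and 0.03. Posterior HOX had 2 measured genes and no median.

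**Figure D3:**
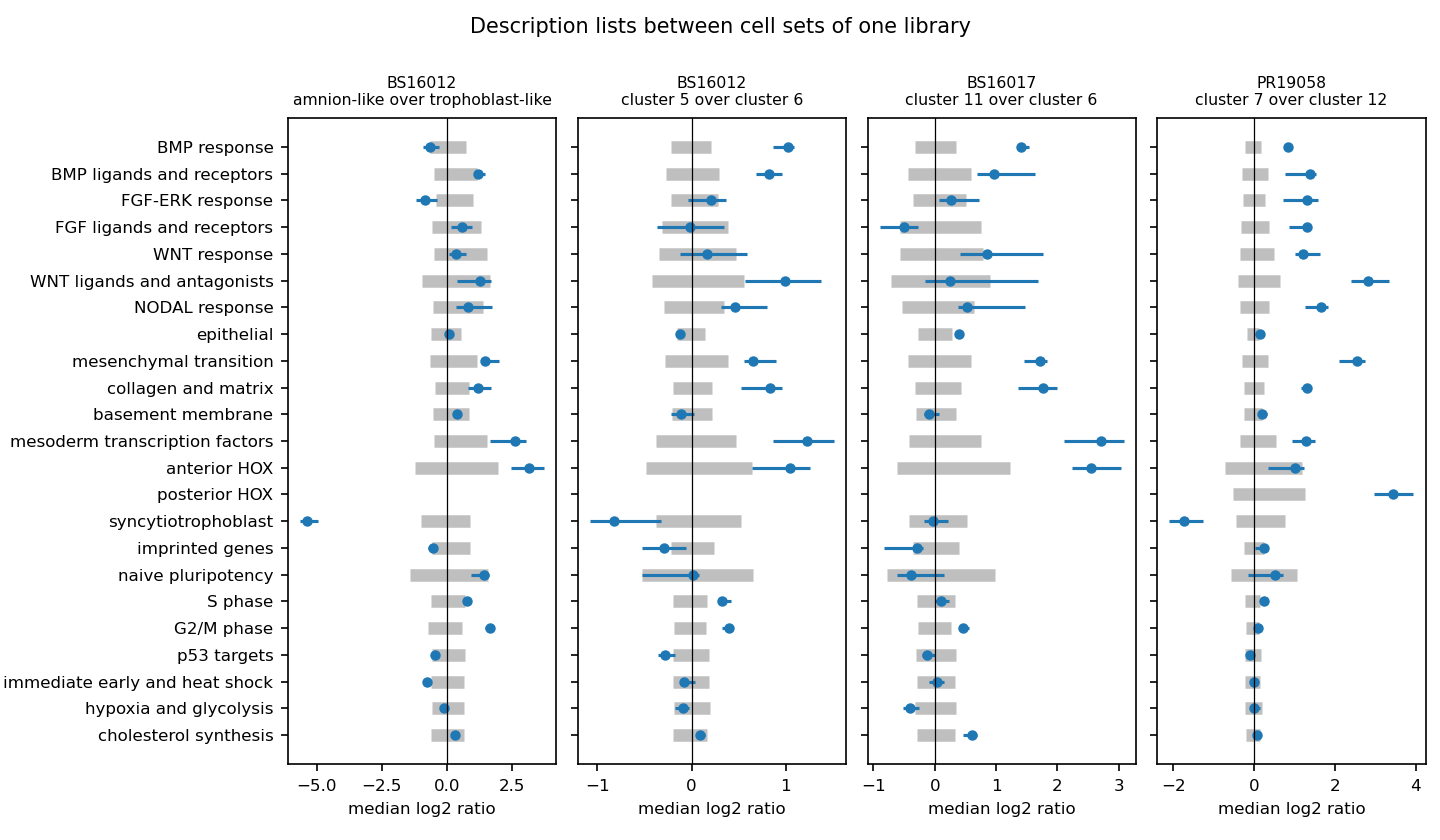
Median log2 ratio (x axis) of each description list (y axis) between cell sets of 1 library, as points with the 95% counting interval, over grey bars that span 95% of 10000 matched random lists. The BMP response is at -0.64 for amnion-like over trophoblast-like cells (0.47 at Leiden resolution 0.5) and at 1.02, 1.41 and 0.85 in the 3 cluster pairs.

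In 1 pair of clusters each of BS16012, BS16017 and PR19058, 1 cluster had more BMP response, mesenchymal and matrix RNA than the other. These pairs of clusters were chosen after the clusters were seen. At Leiden resolution 0.5, clusters 5 and 6 fell into 1 cluster, as did 7 and 12, so the pairs of BS16012 and PR19058 do not exist there. Cluster 5 over 6 in BS16012 had a BMP response median of 1.02 (0.86 to 1.09), with 6 of 11 genes at least 2-fold higher and 1 lower. Cluster 11 over 6 in BS16017 had 1.41 (1.36 to 1.55), with 7 of 11 higher. Cluster 7 over 12 in PR19058 had 0.85 (0.79 to 0.92), with 5 of 12 higher. Mesenchymal transition medians were 0.65, 1.71 and 2.53, the last 2.10 at the bound, and up to 2.79 in BS16017 under other settings. Collagen and matrix medians were 0.83, 1.76 and 1.31, where the second was 1.51 at the bound. Mesoderm transcription factors had 1.22, 2.71 and 1.27, with 1.24 at the bound for the second, which ran from 1.69 to 3.19 under other settings. Epithelial genes moved less, with a median of 0.40 in BS16017. Syncytiotrophoblast medians were -0.82, -0.03 and -1.73, where the second changed sign under other settings, up to 0.06, and the last fell to -2.67. In PR19058 the medians of WNT ligands and antagonists, NODAL response and FGF-ERK response were 2.82, 1.66 and 1.30, and posterior HOX genes reached 3.45, or 1.94 at the bound. There the WNT ligand median ran from 1.47 to 3.52 and the NODAL median from 0.73 to 1.72 under other settings.

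Over these 3 pairs 232 description-list genes were measured in all, and 43 were at least 2-fold apart in the same direction, a criterion chosen after the values were seen. Of these 35 were higher, among them BMP targets and ligands, cadherins of mesenchyme and the intermediate filament VIM. The 8 lower were FGFR1, AXIN2, LAMA1, NR2F2, GDF15, HSD3B1, CDKN1C and PHLDA2. The log2 ratios in BS16012, PR19058 and BS16017 were 3.0, 5.31 and 5.47 for VIM and 1.11, 2.98 and 4.31 for MSX1. They were 1.27, 1.61 and 1.14 for BMP4, and 1.74, 2.09 and 3.57 for TNC. Those of CDKN1C (chromosome 11, 2883213 to 2885773) were -2.88, -3.26 and -2.65, and those of its neighbour PHLDA2 (chromosome 11, 2928273 to 2929455) were -3.28, -1.27 and -3.67. FGFR1 had -1.08, -1.26 and -1.89. VIM stood at 244 against 30.6 CPM in BS16012, 219 against 5.52 in PR19058 and 261 against 5.81 in BS16017. All of these were below the 1265 CPM of VIM in BS16001, where most cells were pluripotent-like. BMP2, LEF1, HAND2, WT1, NR2F1 and FBN1 had 0 UMIs in cluster 6 of BS16017, which has 278 cells there. With these at the 3-count floor, 42 of the 43 genes stayed at least 2-fold apart, 34 higher and 8 lower. NR2F1 did not, at a bound of 0.09.

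**Figure D4:**
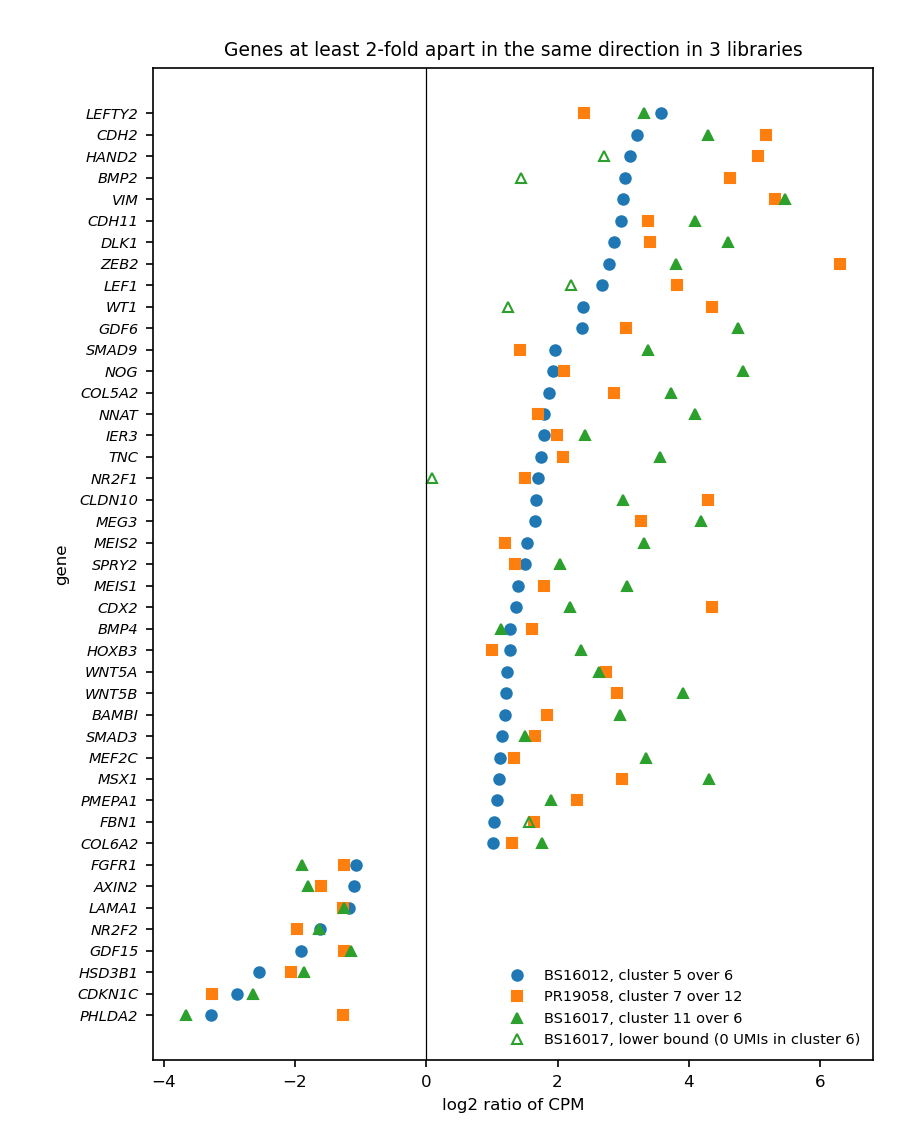
Log2 ratio of CPM (x axis) of the 43 genes (y axis) at least 2-fold apart in the same direction in 3 pairs of clusters, with 1 marker shape per library and open triangles for lower bounds. VIM is at 3.0, 5.31 and 5.47 and CDKN1C at -2.88, -3.26 and -2.65 in BS16012, PR19058 and BS16017.

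After thinning, the genes HAND1 and GATA3 were in the same cell of BS16012 and BS16017 less often than their shares would give. HAND1 is of the mesenchyme list and GATA3 of the trophoblast list. HAND1 and ISL1 were together more often. Independent pairs simulated at the depth of BS16012 and thinned to 2000 UMIs gave ratios from 0.868 to 1.06. A ratio in that range can thus arise without any link between the genes. The simulated pairs were not matched to the number of cells expected for each real pair, so the range is only a rough guide. After thinning to 2000 UMIs, BS16012 had 666 cells with both HAND1 and GATA3 against 827 expected, a ratio of 0.805 (0.751 to 0.862). The ratio was 0.786 (0.743 to 0.830) in BS16017, 0.911 (0.857 to 0.967) in PR19058, 0.742 (0.537 to 0.998) in PR17028 and 1.11 (0.949 to 1.29) in BS16007. Without thinning it was 1.04, 1.06, 1.003 and 1.11 in the first 4, a change of direction, and deep cells hold more of every gene. Both genes were then in 78.8% of cells of BS16012, 54.9% of BS16017, 94.6% of PR19058 and 17.0% of PR17028. At full depth the 2 genes were thus detected in the same barcodes. Doublets were not removed and free RNA was not tested, so whether they mark separate cells stays open. In PR19058 the single shares were 97.0% and 97.2%, so its ratio could hardly leave 1. HAND1 and ISL1 had a ratio of 1.55 (1.40 to 1.70) in BS16017, and ISL1 and GABRP 1.44 (1.28 to 1.61). SOX2 and HAND1 had 0.576 (0.357 to 0.878) in BS16001 and 0.620 (0.465 to 0.810) in BS16007, but 1.06 and 0.975 without thinning. At 4000 UMIs, HAND1 and GATA3 had 0.905 (0.867 to 0.943) in BS16012 and 0.899 (0.866 to 0.931) in BS16017, a depth that was not simulated. EPCAM and COL3A1 had 1.51 (1.34 to 1.70) in BS16017 but 0.509 (0.254 to 0.909) in PR19058 and 0.872 (0.477 to 1.46) in BS16012. TBXT was in none of the thinned cells of any library, and pairs with TBXT or FOXF1 could not be estimated.

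HAND1 was seen in 66.5% of thinned cells of cluster 5 in BS16012 and in 86.1% of cluster 11 in BS16017. Cluster 8, of trophoblast-like cells, gave 7.73% and 5.80%. Whether HAND1 was expressed there or came from free RNA was not tested. Unthinned, the shares were 97.3% and 98.1% against 56.4% and 41.7%, at medians of 27926.5 and 18521 UMIs against 46543 and 35032. GATA3 was in 86.8% of thinned cluster 8 cells of BS16012, and in 10.2% of the pluripotent-like cluster 0 of BS16001 at a median of 32805 UMIs, or 66.7% unthinned. ISL1 was in 15.7% of cluster 11 and 0.893% of cluster 8 in BS16017, or 65.6% and 10.8% unthinned. COL3A1 was in 15.8% and 1.12%, or 52.0% and 8.55%. CGA was in 99.0% of thinned cluster 11 cells, so a UMI of CGA does not separate trophoblast from other cells of BS16017. Free RNA in droplets can give such a share.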

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

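Removing the highest Scrublet scores and comparing clusters by number were chosen after the data were seen; the other settings were not. Depth limits PR17028 most, where a count of 0 allows 0.0848 CPM. PR17028 kept 2055 cells in the report, 3354 with all deposited barcodes and 1077 under the stricter filter. Its median genes per cell were 2581, 889.5 and 3686 in that order. BS16017 kept 5819 cells in the report and 3849 under the stricter filter. Gene levels depended on the cells kept in some libraries: of 765 levels of at least 5 CPM, 651 stayed within their counting interval with all deposited barcodes, 547 under the stricter filter and 765 with doublet calls kept. Under the stricter filter 110 of 145 levels of BS16017 left it, 53 of 132 of BS16012 and 52 of 127 of PR17028, at ratios down to 0.693. TMM factors moved them by 0.831 to 1.30 times and DESeq2 size factors by 0.842 to 1.41 times. Clusters numbered 16 in the report, 10 at resolution 0.5, 28 at 2, 15 with doublet calls kept and 13 under the stricter filter. Class shares shifted under all of these, and the cause was not tested. In PR17028, however, 0 doublets were called, so keeping the calls left its cells the same. Its trophoblast-like share was still 97.9% there against 74.65% in the report, so the grouping and naming of cells moved it.

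The class shares in percent follow by setting. Resolution 0.5 gave amnion-like cells in BS16012 65.5, pluripotent-like 92.0 in BS16001 and 2.98 in BS16007, smooth muscle-like 94.6 in PR19058 (0 in the report), and trophoblast-like 29.1 in BS16012, 37.3 in BS16017, 98.3 in PR17028 and 3.72 in PR19058. Resolution 2 gave extra-embryonic mesenchyme-like 9.07 in BS16017 (0 in the report), pluripotent-like 61.6 and 3.41, and trophoblast-like 12.8 in BS16012, 28.1 in BS16017 and 94.5 in PR17028. Highly variable genes with the description lists gave amnion-like 54.6, pluripotent-like 98.1 and 3.87, smooth muscle-like 58.9 in PR19058, and trophoblast-like 11.8 in BS16012 and 97.1 in PR17028. Each library on its own gave amnion-like 19.1, pluripotent-like 74.9 and 0, smooth muscle-like 19.7 in PR19058, and trophoblast-like 4.34, 41.1, 91.8 and 15.6. Doublet calls kept gave amnion-like 55.8, pluripotent-like 90.2 and 1.90, and trophoblast-like 13.5, 34.1, 97.9 and 3.48. The stricter filter gave amnion-like 66.1, pluripotent-like 51.4 and 1.44, and trophoblast-like 18.3 in BS16017 and 91.3 in PR17028. Highest scores removed gave amnion-like 46.7, pluripotent-like 90.2 and 1.78, and trophoblast-like 12.1 in BS16012 and 97.4 in PR17028. Shares of these classes and libraries that are not listed for a setting stayed within their counting interval, and those classes in other libraries stayed at or under 5.35.

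For amnion-like over trophoblast-like cells, mesenchymal transition was 1.27 over members with at least 50 UMIs and 1.32 at resolution 0.5, and collagen and matrix 0.79 at resolution 2. Syncytiotrophoblast was -3.38 at resolution 0.5, -5.66 at 2 and -4.88 thinned, and G2/M phase 1.77 without mitochondrial and ribosomal-protein genes, 0.64 at resolution 0.5 and 1.45 at 2. BMP response changed sign to 0.47 at resolution 0.5, and FGF ligands and receptors to -0.61 thinned. FGF-ERK response changed sign, to 0.07001 at resolution 0.5 and 0.24 thinned, and the cause was not tested. The BMP response was 1.16 for clusters 5 over 6 at resolution 2, 1.29 without mitochondrial and ribosomal-protein genes, 1.56 at resolution 2 and 1.60 thinned for 11 over 6, and 1.34 at resolution 2 and 0.76 thinned for 7 over 12. Collagen and matrix for 7 over 12 was 1.46 at resolution 2 and 1.45 thinned. At resolution 0.5 clusters 5 and 6, 7 and 12, 4 and 1, and 13 and 8 each fell into 1 cluster, so those pairs gave no value. Between the shallow clusters of BS16017, resolution 2 reversed cluster 9 over 8 for BMP response (-0.59), mesenchymal transition (-0.30) and G2/M phase (-0.56), and cluster 14 over 8 for S phase (0.21). The cause was not tested. Of all list medians under these settings, 708 stayed within their interval, 276 moved beyond it, some of them across 0, and 6 that stood apart from random lists reversed.

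Without thinning, the point value of the ratio of cells with both genes changed side in 7 cases. It became 1.06 for SOX2 and HAND1 in BS16001, 1.04, 1.06, 1.003 and 1.11 for HAND1 and GATA3 in BS16012, BS16017, PR19058 and PR17028, 1.34 for CDH1 and VIM in BS16017, and 1.012 for POU5F1 and GATA3 in PR19058. It moved to 0.975 for SOX2 and HAND1 in BS16007. Deep cells hold more of every gene, which can raise an unthinned ratio. Independent pairs simulated at the depth of BS16012 gave a median of 1.10 without thinning. CDH1 and VIM in BS16017 lay beyond this, with an interval of 1.26 to 1.42, and no pairs were simulated at that library's depth. There, depth also differed between clusters, with medians of 2140 UMIs in cluster 9 and 35032 in cluster 8. In PR19058, HAND1 and GATA3 were in 97.0% and 97.2% of cells, so their ratio could hardly leave 1. How much depth added in each case was not tested. Thinned to 4000 UMIs, HAND1 and GATA3 had 0.905 in BS16012 and 0.899 in BS16017, and EPCAM and COL3A1 had 1.26 in BS16017.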

Other observations

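The tests on the barcode set, on nuclei in cluster 14 and on the shared contrast were chosen after the result was seen, as were the pairs of clusters; the others were not. No biological explanation was tested, since no label puts the libraries in groups.

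Of the 4 trophoblast-like clusters in PR17028, cluster 15 had more RNA of dividing cells than cluster 8, and cluster 8 more of syncytiotrophoblast. Cluster 15 over cluster 8 had a G2/M phase median of 2.17 and a syncytiotrophoblast median of -3.41, with 10 of 11 genes at least 2-fold lower. Its BMP response median was -1.10, its FGF-ERK response median -1.89 and its immediate early median -1.87. Basement membrane genes were higher, at 1.14. In BS16017, the unnamed cluster 11 over cluster 8 had 3.0 for G2/M phase, 1.46 for S phase and 2.12 for mesenchymal transition. Clusters 9 and 14 over cluster 8 in BS16017 had more syncytiotrophoblast RNA, at medians of 1.42 and 0.73.

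In BS16007, which was mostly unnamed, cluster 4 over cluster 1 had medians of 0.24 for the BMP response and 0.36 for the FGF-ERK response, the latter 0.25 to 0.55 under other settings. FGF ligands and receptors went the other way, at -0.44, and stayed between -0.48 and -0.35. WNT response, at 0.05, and NODAL response, at 0.19, changed sign under other settings, down to -0.15 and -0.05. Across 7058 genes, which are not independent replicates, the log levels of BS16001 and BS16007 had r of 0.953, those of BS16012 and PR19058 0.913, and those of BS16001 and PR17028 0.562, the lowest of all pairs of libraries.

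Ribosomal-protein genes took 20.5% of UMIs in PR19058, a lower share than elsewhere. The barcodes of PR19058 may come from another barcode list than the others: only 1 was shared in its 5 pairs with other libraries, against 283 in the other 10 pairs, a ratio of 0.00964 per product of barcode numbers. A different chemistry could go with this, but no label states one, and it was not shown to set the ribosomal share. Cluster 8 was used to ask whether all cell populations are shifted. Its PR19058 cells had a median of 20.1%, 2.13 points above BS16017, the lowest of the other libraries. It was below the 25.6% of BS16012 and the 22.05% of PR17028. A share at or above the lowest was set beforehand as the outcome against a library-wide difference, and it was met. The quartiles of PR19058 and BS16017 overlapped, so such a difference is not ruled out.

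Shallow barcodes with trophoblast genes in BS16017 may be of more than 1 kind. In cluster 14, MALAT1 and NEAT1 made up 23.8% of UMIs, 11.6 times the share in cluster 8, and mitochondrial UMIs 0.891% against 3.75%. Nuclei or cells that lost cytoplasm could give such values. NEAT1 is among the genes that lead cluster 14, so its high share partly restates what was seen before the test was chosen. In cluster 9 the MALAT1 and NEAT1 share was 1.16 times that of cluster 8, under the bound of 1.2 set beforehand. This argues against nuclei as its whole content. Mitochondrial UMIs were lower there too, at 1.52%, which goes the other way. Free RNA stays open for both: 40 abundant genes of cluster 11 stood at a median of 0.233 of their library level in cluster 14 and 0.318 in cluster 9. Free RNA alone was taken to need at least 0.5, and to be ruled out with the median and at least 75% of the genes under 0.25. In cluster 14, 65% of the 40 genes were under 0.25, and in cluster 9 27.5%.

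The largest clusters of PR19058 may differ along the same line as clusters 5 and 6 of BS16012. Across 236 description-list genes, which are not independent, the log2 ratios of cluster 7 over 12 and of cluster 5 over 6 had a Pearson's r of 0.745, and all 47 genes at least 2-fold apart in both had the same direction, also with counts of 0 at their floor. For cluster 11 over 6 in BS16017, where cluster 6 is the same cluster with other cells, r was 0.769 with the pair of BS16012 and 0.608 with that of PR19058, or 0.723 and 0.609 at the floor. A shared treatment could not be tested without the labels.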
